A study of Rattus norvegicus with 15 samples.

How the data were processed

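RNA-seq values of prostate tissue from 15 samples of SD rats were used, 5 each in the groups Control, Model and LIPUS. Total RNA was extracted with TRIzol and libraries were made with the VAHTS Universal V5 kit, per the labels' protocols. The deposited table gives FPKM, fragments per kilobase of gene scaled to library size, for 22436 genes (18127 protein coding and 4309 non-coding), 1 value per gene and sample. Per the submitters' processing notes, fastp, HISAT2, SAMtools, HTSeq, R 3.2.0 and DESeq2 were used with the rat genome build rn6. The notes state no role or order for these tools, and the strand of the libraries is not stated. Gene symbols and gene numbers are those of the deposited table. A gene table of a later rat build served for names and synonyms only.

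Reads per gene were recovered from the deposited FPKM by a search for the gene length and library size at which every value of a gene becomes a whole number. All 22436 genes gave whole reads within 0.001 in every library. For a gene with a value above 0 in a single library this is no check, since many numbers of reads fit. The search then gives the smallest number that leaves a whole gene length. On simulated data the search returned every read count of 99.9% of 19787 genes. Recovered reads served for depth, library composition, detection floors and an alternative test. Libraries held 29675962 to 36402094 reads. A count of 0 was taken to allow up to 3 reads, which is 0.0412 to 0.0505 FPKM for a gene of 2 kb and covers counting error only. No library was a copy of another: the lowest chi-square per degree of freedom between the reads of 2 libraries of a group was 80.3.

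Genes above 0.5 FPKM in at least 5 of the 15 samples were tested, 12490 in number. Values as deposited were turned into log2(FPKM + 0.1) and fitted in R 4.3.3 with limma 3.58.1, with all 15 samples in 1 fit, 1 mean per group, an empirical Bayes estimate of the spread with an intensity trend, and Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05, and counts at an absolute log2 change of at least 1 stand beside it. Comparisons were Model against Control, LIPUS against Model and LIPUS against Control. The spread pools samples of all groups and assumes that they vary alike. Library make-up did not vary alike: the SD of the mitochondrial percent of reads was 0.406 in Control, 9.18 in Model and 15.7 in LIPUS. Pooling with Control may thus make p-values of LIPUS against Model too small. Relative log2 changes are log2 changes minus the median over all tested genes, while p-values belong to values as deposited. Median-of-ratios factors came from 10313 genes above 0 in every library. Scaled values are FPKM divided by these factors.

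Gene lists were fixed before the values were seen, 31 in number: Th17 cells, regulatory T cells, IL-1 receptor and MyD88 signalling, T cells, B and plasma cells, macrophages and monocytes, neutrophils, mast cells, chemokines, inflammatory cytokines and mediators, antigen presentation, interferon-stimulated genes, prostate luminal and basal cells, seminal vesicle secretory genes, urothelium, smooth muscle, fibroblasts and extracellular matrix, skeletal muscle, adipocytes, endothelium, Schwann cells and nerve, pain mediators and receptors, immediate early and stress genes, erythrocytes, cell cycle, unfolded protein response, antioxidant genes, mechanosensing and YAP targets, angiogenic and growth factors, and mitochondrially encoded genes. Lists needed 3 tested members, so B and plasma cells (0 tested members) and neutrophils (2 tested members) were left out and 29 were tested. The test was limma's camera with a preset correlation of 0.01 between genes, with camera under an estimated correlation and limma's fry beside it, each adjusted over the 29 lists. Some members had other names in the table, among them the mitochondrial genes, and were matched by synonym. Counts of members adjusted over the list alone use a separate adjustment within each list.

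Library measures, the 10 genes of the series' question, the Th17 and regulatory T cell index and list means per library were tested with two-sided exact permutation tests over the 252 splits of 5 against 5, adjusted within each family. The smallest p such a test can give is 0.00794. Both steps (Model against Control, LIPUS against Model) share the Model samples, so the correlation and covariance were set beside 100 simulations of unchanged groups with shared Model samples and beside 20 divisions of the Model samples into disjoint parts. Named genes followed a rule fixed beforehand: the 10 genes of the series' question, the 8 highest and 8 lowest log2 changes among called genes with a mean of at least 1 FPKM in the higher group and no overlap between groups, up to 4 members with the smallest p of each called list and up to 2 passing members of each other list, and up to 8 genes called in both steps. Symbols that are only locus numbers were passed over. Some genes that met this rule are not reported here.

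The limma procedure was tested on simulated data drawn from the genes' mean levels in Control, their spread within groups and the sizes of the 15 libraries, with 12226 genes tested. It recovered 9.47% of genes changed 2-fold and 70.1% of genes changed 4-fold, 3.75% of calls were unchanged genes, the median estimate for genes raised 4-fold was 2.08 on the log2 scale, and 0 genes were called between unchanged groups. With a single list raised, camera called 0 other lists of 29. The simulated genes varied independently of each other and the groups had no shift in library make-up. These runs therefore cannot tell how the tests behave where genes vary together or libraries differ in make-up. Genes of families with near-identical copies (Klk1c9, RT1, Oas1b, Gbp2, Scgb and Svs genes, haemoglobins) may have reads split between copies.

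Alternatives fixed beforehand were a pseudocount of 1 or 0.01, median-of-ratios scaling, quantile normalization, no filter, a stricter filter (mean of at least 1 FPKM), only the groups compared in the fit, limma's array weights, the replicate number as a block, each library left out in turn, and the other list tests. Alternatives chosen after seeing the data were values relative to nuclear reads, limma-voom on recovered reads, the log2 ratio of ventral to dorsolateral reads in the fit, an estimated correlation on scaled values, and the removal of Model_7 and LIPUS_10 together. Ventral secretory genes (Scgb1d2, Scgb1d4, Scgb2a1) and dorsolateral ones (Pbsn, Msmb) were summed as lobe measures after the libraries had been seen to differ. Figures and other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. All numeric columns of the table were used.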

Results

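The series asked how low-intensity pulsed ultrasound (LIPUS), short bursts of sound waves applied as a physical treatment, changes gene expression in the prostate of a rat model of chronic prostatitis with chronic pelvic pain. Its stated interest is the balance between Th17 cells, a proinflammatory class of helper T cell, and regulatory T cells, which restrain immune responses. RNA-seq was measured in prostate tissue of SD rats in 15 samples: 5 untreated controls (Control), 5 samples of the prostatitis model (Model) and 5 samples treated with ultrasound for 4 weeks (LIPUS). The sample titles give the treatment intensity as 1 W/cm2 and the treatment field gives 1.5 W/cm2, so the intensity is left open here. Samples carry the replicate numbers 6 to 10 in each group. The labels do not say that the samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. The libraries held 29675962 to 36402094 reads, and 0 reads in a gene of 2 kb allowed a level of up to 0.0412 to 0.0505 FPKM, depending on the library and for counting error only.

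The make-up of the libraries differed between the groups before any single gene was considered. Reads of the 13 mitochondrially encoded genes made up 4.23% ± 0.406 (SD, n = 5) of the reads in Control, 34.9% ± 9.18 (SD, n = 5) in Model and 59.6% ± 15.7 (SD, n = 5) in LIPUS. Every Model and every LIPUS library lay above every Control library (two-sided exact permutation p = 0.00794, the smallest that 252 splits can give, adjusted p = 0.0179 over 18 tests of library measures), and LIPUS lay above Model with an exact p of 0.0238 (adjusted p = 0.0476). LIPUS_10 reached 83.3%. Genes with at least 1 read numbered 18532 ± 362 (SD, n = 5) in Control, 15259 ± 794 in Model and 14439 ± 1297 in LIPUS, with an exact p of 0.00794 for each of the latter groups against Control and 0.254 for LIPUS against Model. The prostate has lobes with different secretions. Transcripts of the ventral lobe's steroid-binding protein (Scgb1d2, Scgb1d4 and Scgb2a1) took 15.02% ± 2.80 of Control reads, 1.36% ± 2.19 of Model reads and 4.23% ± 3.47 of LIPUS reads (SD, n = 5), while the dorsolateral products Pbsn and Msmb took 1.62% ± 1.79, 8.21% ± 5.17 and 1.53% ± 1.22. The log2 ratio of ventral to dorsolateral reads was −3.33 ± 6.61 in Model and 3.93 ± 1.82 in Control (exact p = 0.0556, adjusted p = 0.1), and Model_7, at 7.76, stood apart from the other Model libraries, at −9.25 to −2.77. These differences moved with the groups, so they stand beside every gene group described here. As deposited, the median gene shifted by −0.90 on the log2 scale from Control to Model, by −0.60 from Model to LIPUS and by −1.48 from Control to LIPUS. A change relative to the median gene has this shift subtracted and is called a relative change. An adjusted p printed beside a relative change tests the change as deposited, with the shift included, unless it is given as scaled. After median-of-ratios scaling the median gene shifted by −0.15, −0.02 and −0.16.

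**Figure D1:**
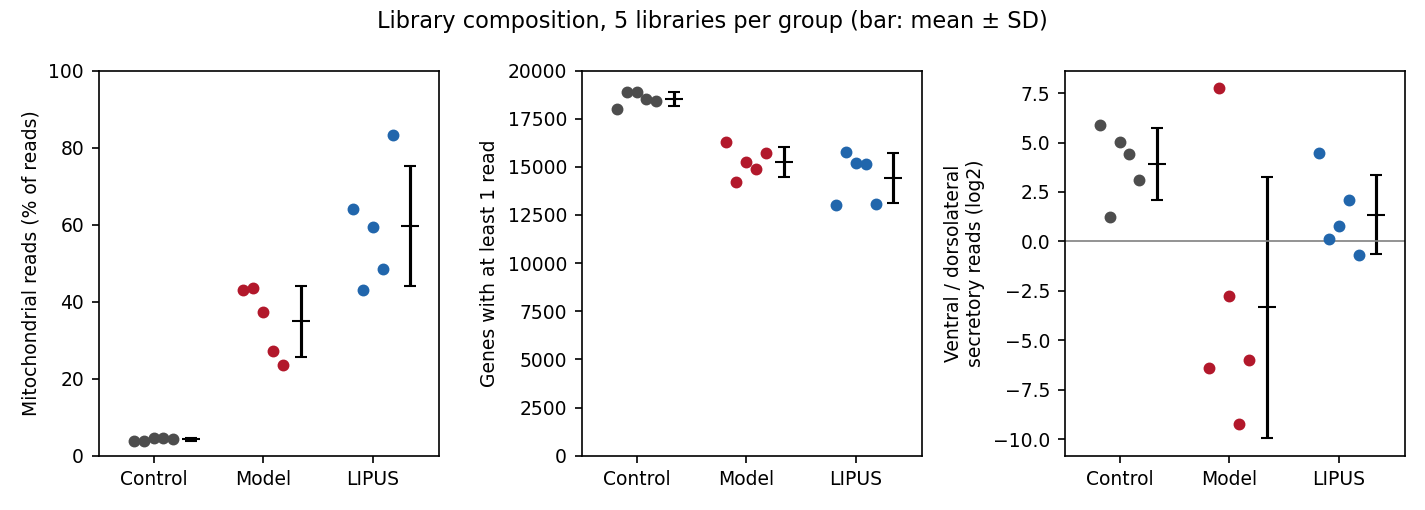
Percent of reads from mitochondrially encoded genes, number of genes with at least 1 read, and log2 ratio of ventral to dorsolateral secretory reads in each library, with the mean and SD of each group (n = 5). The Control libraries lie at 3.75% to 4.69% mitochondrial reads, all below the Model libraries at 23.5% to 43.5%, and LIPUS_10 lies at 83.3%.

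The genes of the series' own question gave no change past the threshold in exact tests as deposited, and several of them were measured at low levels. Some passed after quantile normalization. The cytokine gene Il1b (NCBI gene 24494) was at 0.425 ± 0.328 FPKM in Control, 0.936 ± 0.579 in Model and 0.735 ± 0.622 in LIPUS (SD, n = 5). Its receptor gene Il1r1 (25663) was at 5.18 ± 0.638, 6.28 ± 3.38 and 1.45 ± 1.16 FPKM, and the adaptor gene Myd88 (301059) at 7.37 ± 0.258, 5.63 ± 2.14 and 4.12 ± 2.42 FPKM. Tgfb1 (59086), a growth factor gene that regulatory T cells use, was at 4.96 ± 0.956, 2.08 ± 1.30 and 2.04 ± 0.842 FPKM. None of the 30 exact permutation tests (10 genes in 3 comparisons) passed after Benjamini-Hochberg adjustment: 5 had an exact p under 0.05 before it. The smallest adjusted p was 0.0794. After quantile normalization 11 of the 30 passed. Among them were Il1b, higher in Model than in Control (adjusted p = 0.0433), and Foxp3, Il17a, Il6 and Il10, higher in Model and in LIPUS than in Control (adjusted p = 0.0238 each). Il17a, Il6 and Il10 had 0 to 10 reads per group, and quantile normalization gave libraries without a read of them a higher value in Model and LIPUS than in Control. The same limit holds for Foxp3 in LIPUS, where 2 of 5 libraries had reads of it. As deposited, its mean was lower in LIPUS than in Control (0.0561 and 0.0701 FPKM). As deposited, those 5 were Tgfb1 in Model and in LIPUS against Control, Il1r1 in LIPUS against Model and against Control, and Myd88 in LIPUS against Control, all with lower values in the group named before "against". In the limma fit over all 12490 tested genes, Il1r1 was lower in LIPUS than in Model (adjusted p = 0.0293, scaled 0.101). Its log2 change was −2.02 as deposited and −1.42 relative to the median gene (SE 0.54). Tgfb1 was lower in Model than in Control (adjusted p = 0.0153, scaled 0.204). Its log2 change was −1.45 as deposited and −0.55 relative to the median gene (SE 0.45). Myd88 passed in limma in LIPUS against Control (adjusted p = 0.0209), as did Tgfb1 (adjusted p = 0.0138) and Il1r1 (adjusted p = 0.00317). The log2 change of Myd88 turned from −1.02 to 0.38 and that of Tgfb1 from −1.34 to 0.04 after scaling. Il17a, the cytokine gene that names Th17 cells, had 1 recovered read in all 5 Control libraries together and 0 reads in the Model and LIPUS libraries. Il6 had 4, 0 and 0 reads and Il10 had 2, 0 and 10 reads. Il17a and Il6 each had reads in a single library, so their numbers in Control are the smallest that fit. Foxp3, the master regulator of regulatory T cells, had 51, 105 and 38 reads per group, and Tnf had 43, 16 and 20. None of these 5 genes had an exact p under 0.05 as deposited in any comparison.

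**Figure D2:**
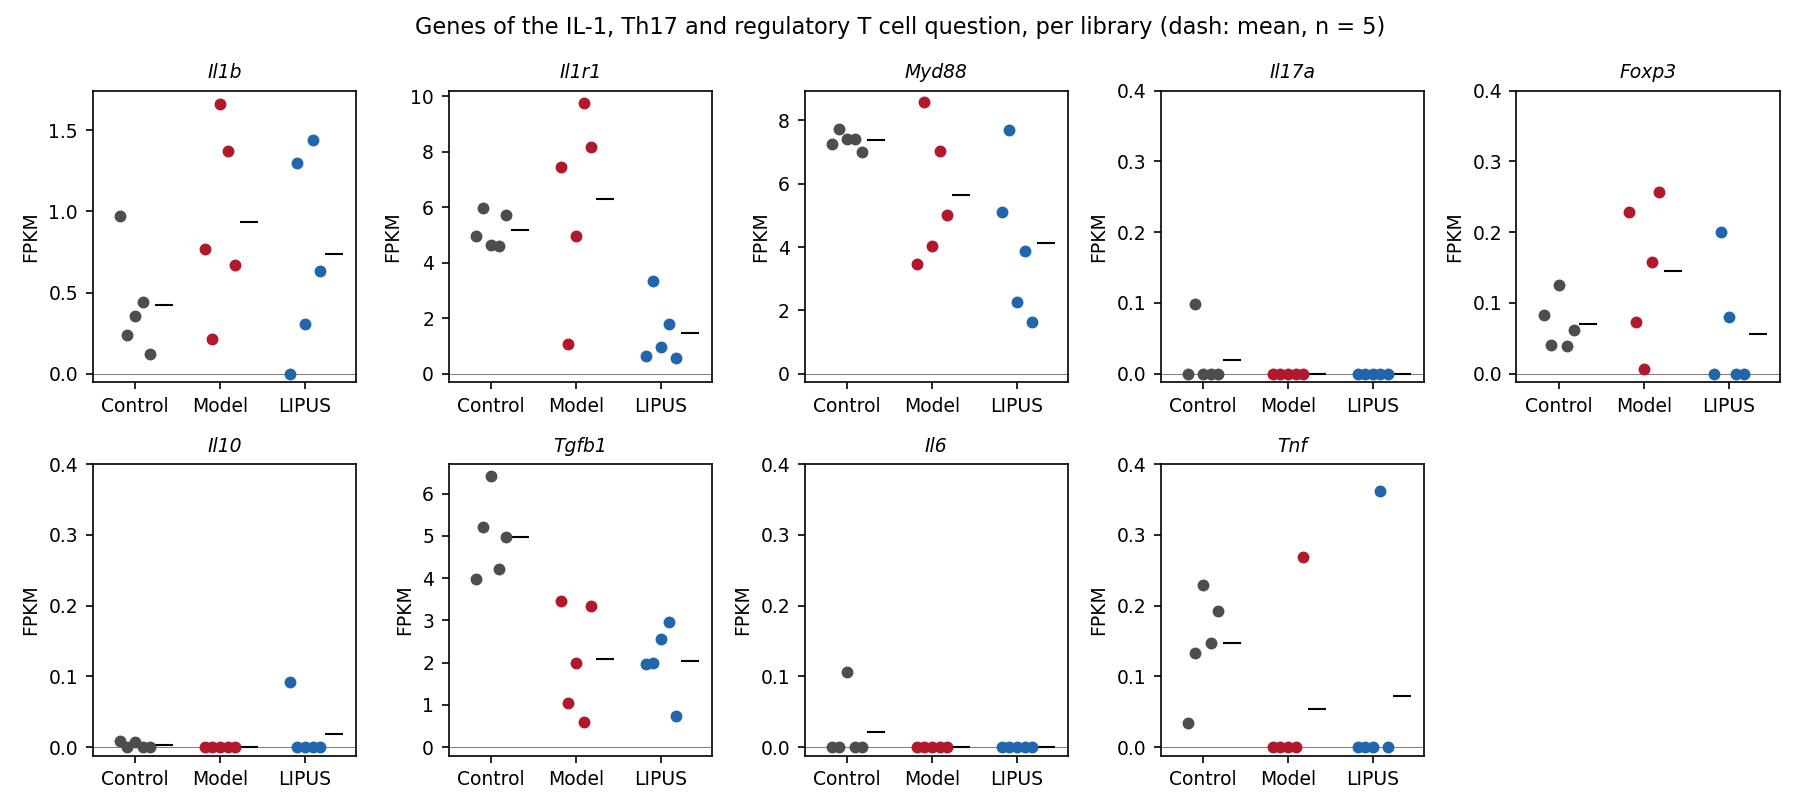
FPKM of 9 genes tied to the series' question in each of the 15 libraries (points), with the group mean as a dash (n = 5). Il17a, Il6 and Il10 lie at or near 0 in all groups, and the LIPUS libraries lie at 0.569 to 3.33 FPKM for Il1r1 against 4.60 to 5.98 in Control.

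An index of the Th17 and regulatory T cell balance, the mean log2 level of 6 measured Th17 genes minus that of 7 measured regulatory T cell genes, was −1.02 ± 0.31 in Control, −0.92 ± 0.58 in Model and −0.92 ± 0.42 in LIPUS (SD, n = 5). The differences were 0.11 for Model against Control (exact p = 0.738), −0.00179 for LIPUS against Model (exact p = 1) and 0.11 for LIPUS against Control (exact p = 0.643), with an adjusted p of 1 each. They lay within the spread between samples and changed sign under several settings. The index rests on genes that many other cells express: Stat3, Stat5a and Stat5b took most of the reads of its members, while Il17a and Foxp3 were too low to enter it. Each gene of a list counts alike in the index whatever its reads, so a low gene such as Il23a (71 to 188 reads per group) weighs as much as Stat3.

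Compared with Control, Model prostates held far less transcript of dividing cells and of connective tissue, relative to the median gene. All 17 cell cycle genes and 19 of 21 fibroblast and extracellular matrix genes fell (15 each after scaling; camera adjusted p = 6.35e-12 and 3.53e-10). With an estimated correlation the adjusted p was 0.0393 and 0.361 (scaled, 0.00155 and 0.451). Top2a (360243), which untangles DNA during division, went from 14.95 ± 4.02 FPKM in Control to 0.0205 ± 0.0458 in Model (SD, n = 5; relative log2 change −6.09, SE 0.35, adjusted p = 3.2e-09). Rrm2, a subunit of the enzyme that makes DNA building blocks, fell from 11.6 ± 5.30 to 0.0207 ± 0.0464 FPKM, and cyclin A2 (Ccna2) from 7.84 ± 2.37 to 0.0241 ± 0.0394. The spindle checkpoint kinase Bub1 had a relative change of −3.81. Among the matrix genes, collagen I (Col1a1, 29393) went from 177 ± 63.1 to 1.89 ± 1.14 FPKM (relative change −5.71, SE 0.38, adjusted p = 1.24e-08), collagen III (Col3a1) from 313 ± 91.4 to 7.35 ± 2.85 FPKM, and periostin (Postn) and collagen VI (Col6a1) had relative changes of −3.26 and −3.83. Endothelial genes fell for 8 of 10 members (5 scaled; adjusted p = 0.776 with an estimated correlation), with Cdh5, the cadherin of vessel walls, at a relative change of −2.86 and Pecam1 at −1.59. Adipocyte genes fell for 8 of 9 (5 scaled; adjusted p = 0.724 with an estimated correlation), among them Lpl (relative change −4.41) and Adipoq (−4.63). Basal epithelial genes fell for 9 of 9 (5 scaled; 0.724 by the same test), among them the keratins Krt5 (−2.49) and Krt14 (−1.96). In the list of mechanosensing genes and targets of the transcription regulator YAP, 12 of 16 fell (9 scaled; 0.724 by the same test), among them the pressure-gated channel Piezo1 (−2.49), Rock2 (−1.48), Itga5 (−1.97) and Yap1 (−0.97).

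The 13 mitochondrially encoded genes all rose from Control to Model. ND3 (26199) went from 2413 ± 218 to 41393 ± 9663 FPKM (SD, n = 5; relative change 4.97, SE 0.29, adjusted p = 8.51e-08), and COX2, COX3 and ND6 had relative changes of 4.69, 3.97 and 3.88. They made up 4 of the 8 genes with the highest change among called genes without overlap between the groups and with a mean of at least 1 FPKM in the higher group. The other 4 were Best1 (a chloride channel, 1.52 ± 0.465 to 28.9 ± 14.7 FPKM, relative change 4.83), Pdzk1ip1 (4.20), Gnrh1 (gonadotropin-releasing hormone, 4.11) and Ccdc152 (3.82). The 8 lowest among these were Pclaf (a replication factor, −6.26), Top2a, Col1a1, Rrm2, Igfbp5 (−5.56), the kallikrein Klk1c9 (−5.45), the spermine-binding protein gene Sbp (−5.42) and Lao1 (−5.29). Klk1c9 belongs to a gene family whose reads can be split between near-identical copies.

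As deposited, camera called no immune list between Model and Control, although single members passed and the mast cell list passed an exact test of its mean. The macrophage list had 5 of 15 members lower (3 higher and 2 lower after scaling), among them Cd14 (relative change −1.07) and Csf1r (−1.53), and was not called (camera adjusted p = 0.412). The interferon-stimulated list had 5 of 22 lower (4 higher and 1 lower after scaling; adjusted p = 0.0902), among them Ifit1 (−2.58) and Gbp2 (−0.26; scaled, adjusted p = 0.296). Mast cell genes had 5 of 8 lower (3 scaled; adjusted p = 0.107) and a scaled list mean 1.56 below Control on the log2 scale (exact p = 0.00794, adjusted p = 0.0276), among them carboxypeptidase A3 (Cpa3), from 9.02 ± 1.45 to 0.511 ± 0.151 FPKM. The T cell list had Cd3g higher (relative change 2.52) and Cd4 lower (−0.89; scaled, adjusted p = 0.0821), and was not called (adjusted p = 0.327). In the list of luminal secretory cells, 7 of 16 fell (3 higher and 6 lower after scaling) and the list was not called (adjusted p = 0.937; its test pointed up while its median and mean log2 changes were −1.18 and −2.23), although its scaled mean passed the exact test (−1.45, adjusted p = 0.0276): the ventral product Scgb2a1 had a relative change of −4.74. This list holds ventral secretory genes such as Scgb2a1, whose reads were fewer in Model, but their part in its change was not tested on its own. With the ventral to dorsolateral ratio in the fit, the relative median of the list went further down, from −0.28 to −1.66. Scgb1d2, Scgb2a1, Pbsn and Msmb belong both to this list and to the ratio. That fit therefore cannot tell a change in lobe mixture from a change in luminal genes. Smooth muscle genes had 8 of 14 lower (3 scaled; adjusted p = 0.242), with Acta2 from 517 ± 227 to 27.1 ± 18.2 FPKM (relative change −3.51) and Synpo2 at −4.02. Adjusted over the list alone, the lower members numbered 6 for mast cells, 9 for smooth muscle and 2 for T cells. The other counts of these lists were the same.

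In numbers, limma called 5750 of 12490 genes between Model and Control (368 higher, 5382 lower; 5255 at 2-fold or more; 6722 at an unadjusted p under 0.05), and the groups did not overlap in 5570 of the tested genes, 44.6% where chance gives 0.794%. The split follows the median shift: after median-of-ratios scaling it was 1911 higher and 2522 lower, after quantile normalization 2527 and 2121, and relative to nuclear reads 1244 and 2854. Scaled and unscaled fits shared 2890 calls in the same direction and none in opposite directions. Of 29 lists, camera called 8, 2 up and 6 down: mitochondrially encoded genes (adjusted p = 2.45e-34) and seminal vesicle genes (0.0184) up, and cell cycle (6.35e-12), extracellular matrix (3.53e-10), mechanosensing (0.00437), basal (0.0184), adipocyte (0.0184) and endothelial genes (0.019) down. The member counts of these 8 lists were the same when adjusted over the list alone. With an estimated correlation between genes, the calls that held were cell cycle (adjusted p = 0.0393) and mitochondrial genes (adjusted p = 0.0393), and the other 6 had an adjusted p of 0.361 (extracellular matrix), 0.724 (mechanosensing, basal, adipocyte and seminal vesicle) and 0.776 (endothelial). On scaled values cell cycle alone held (adjusted p = 0.00155), and mitochondrial genes did not (0.451). In an exact permutation test of the scaled list mean per library, all 5 Model libraries lay on the same side of every Control library for 7 of the 8 lists (exact p = 0.00794, adjusted p = 0.0276 over 87 tests), the exception being the seminal vesicle list. Of the 21 lists that camera did not call, 4 separated the groups in the same way, all lower in Model: mast cells, luminal cells, Schwann cells (−1.31) and pain mediators and receptors (−0.96; adjusted p = 0.0276 each). Since 44.6% of single tested genes separated these groups as deposited, separation alone does not set a list apart from other genes. The seminal vesicle list had 0 of 6 members called (0 adjusted over the list alone), and scaling ended its call (adjusted p = 0.456). With the ventral to dorsolateral ratio in the fit its relative median turned from 1.76 to −2.24 and its call ended (0.688), as it did without Control_6, Model_6, Model_10 or LIPUS_10 (0.0682, 0.117, 0.0598 and 0.0629). The endothelial call ended without Model_7 or LIPUS_10 (adjusted p = 0.0947 and 0.0648), and the basal call without Control_7, Control_8, Model_7 or LIPUS_10 (0.0612, 0.0652, 0.0947 and 0.0629). The adipocyte call ended without Control_6, Control_8, Control_9, Control_10, Model_7 or LIPUS_10 (0.0682, 0.113, 0.117, 0.0828, 0.0696 and 0.0831). With only the groups compared in the fit, and with array weights, the basal (0.134 and 0.231), adipocyte (0.231 and 0.513) and endothelial calls (0.19 and 0.233) ended as well. A pseudocount of 0.01 ended the basal (0.0711), endothelial (0.0957), adipocyte and seminal vesicle calls (0.0542 each). The basal call also ended with the stricter filter (0.121), and the adipocyte call with a pseudocount of 1 (0.0538) and with limma-voom (0.141).

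**Figure D3:**
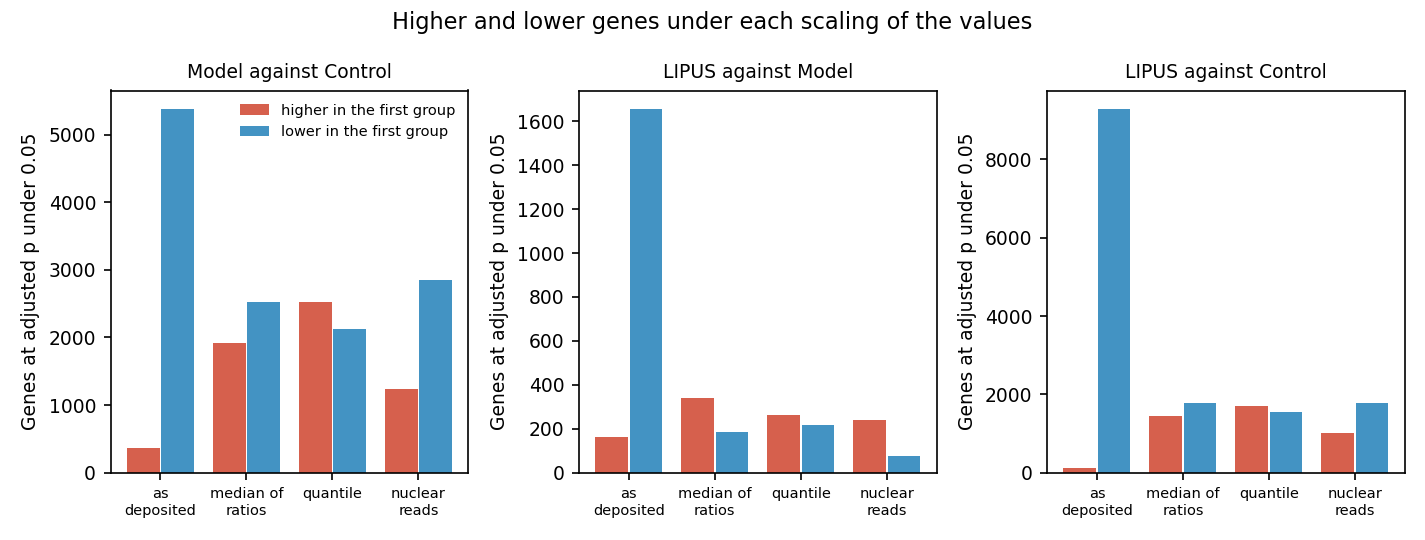
Number of genes with a limma adjusted p under 0.05 that were higher or lower in the group named before "against", for the values as deposited and under 3 other scalings. For Model against Control the split goes from 368 higher and 5382 lower as deposited to 2527 and 2121 after quantile normalization.

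LIPUS samples carried more macrophage transcript than Model samples, relative to the median gene. Of 15 macrophage genes, 6 rose (7 adjusted over the list alone), and the list kept its camera call with an estimated correlation as deposited (adjusted p = 0.0155) but not after scaling (0.185). Camera also called interferon-stimulated, chemokine and antigen presentation genes, each with 2 members that rose. None of these 3 calls held with an estimated correlation (adjusted p = 0.228, 0.183 and 0.244). The exact test of the list means passed for macrophage and interferon genes (adjusted p = 0.0276 each) and failed for chemokines (0.074) and antigen presentation (0.0921). Among the macrophage genes that rose were the complement genes C1qb (29687), from 12.3 ± 4.57 to 25.1 ± 3.78 FPKM (SD, n = 5; relative change 1.70, SE 0.29, adjusted p = 0.0293), and C1qc, from 13.6 ± 4.41 to 26.7 ± 7.03 FPKM (1.58). The macrophage growth factor receptor Csf1r went from 0.967 ± 0.550 to 3.26 ± 1.26 FPKM (2.45), and the mannose receptor Mrc1 had a relative change of 1.72. Of 22 interferon-stimulated genes, 2 rose (2 adjusted over the list alone, 7 after scaling): the transcription factor Irf7 (293624), from 11.5 ± 3.85 to 45.9 ± 35.1 FPKM (relative change 2.29, SE 0.45, adjusted p = 0.0293), and Gbp2 (1.80). Isg15 was at 4.05 ± 2.91 and 22.3 ± 33.7 FPKM and Oas1b at 0.743 ± 0.745 and 3.95 ± 5.52, neither past the threshold (adjusted p = 0.0808 and 0.0626). Among chemokines, the B cell attractant Cxcl13 (1.97 ± 1.53 to 13.0 ± 7.44 FPKM, relative change 3.82) and Ccl7 (2.57) rose, 2 of 14, while Ccl2 was at 0.429 ± 0.594 and 3.39 ± 3.84 FPKM (adjusted p = 0.0901). Among antigen presentation genes, the class II gene RT1-Bb (0.330 ± 0.0821 to 1.76 ± 0.688 FPKM, relative change 2.65) and the peptide transporter gene Tap2 (2.15) rose, 2 of 16 (4 adjusted over the list alone). Among mast cell genes Cpa3 rose, 1 of 8 (2 adjusted over the list alone; relative change 3.01; list, adjusted p = 0.228 with an estimated correlation). RT1, Oas1 and Gbp genes belong to families whose reads can be split between near-identical copies. LIPUS_8 held all the reads of Ifit1 in its group, at 3.36 FPKM.

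Cell cycle genes were higher in LIPUS than in Model for 4 of 17 members (4 adjusted over the list alone; camera adjusted p = 0.136 with an estimated correlation), at levels still far below Control. Ccna2 (114494) was at 0.737 ± 0.425 FPKM against 0.0241 ± 0.0394 in Model (relative change 3.27, SE 0.37, adjusted p = 0.00918), and Top2a at 0.194 ± 0.104 against 0.0205 ± 0.0458 (1.88), where Control had 14.95 ± 4.02. Rrm2 and Bub1 had relative changes of 2.21 and 1.80. Mitochondrially encoded genes rose for 7 of 13 (10 adjusted over the list alone; camera adjusted p = 0.152 with an estimated correlation), among them ND2 (2.05), ND5 (2.19), ND1 (1.68) and ND4L (1.97), beside the higher mitochondrial share of the LIPUS libraries. By the same limits on overlap and level, the 8 highest changes were in Degs2 (4.88), Fcgbpl1 (4.76), the adhesion molecule P-selectin (Selp, 25651; 0.132 ± 0.126 to 3.18 ± 0.901 FPKM, 4.54), cathepsin E (Ctse, 4.36), Lrcol1 (4.23), the cell surface gene Cd52 (47.6 ± 35.4 to 368 ± 92.5 FPKM, 4.20), Zcchc12 (4.03) and Gsdma (3.82). The 8 lowest by these limits were Gnmt (−2.02), Endog (−1.93), Adssl1 (−1.88), Hspa2 (−1.80), Haspin (−1.78), Cyb5r2 (−1.77), Nek3 (−1.70) and Acsl4 (−1.65). Scaling ended the call of Cd52 (adjusted p = 0.0534), Gnmt (0.0956), Endog (0.0513), Adssl1 (0.154), Hspa2 (0.0557) and Haspin (0.0558). Single genes passed in lists that were not called: the growth factor Egf rose (relative change 2.95), the lymphatic growth factor Vegfc fell (−2.74), as did the tight junction gene Cldn5 (−2.27; scaled, adjusted p = 0.0682), the protease receptor gene F2rl1 (−1.34; scaled, 0.087) and the stress genes Herpud1 (−1.04; scaled, 0.23) and Xbp1 (−0.50; scaled, 0.21). Batf, a transcription factor of Th17 and other T cells, rose (2.74), while Ahr had a relative change of −0.85 (scaled, adjusted p = 0.189).

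Between LIPUS and Model limma called 1820 of 12490 genes (163 higher, 1657 lower; 1639 at 2-fold or more; 4705 at an unadjusted p under 0.05), with 340 higher and 186 lower after median-of-ratios scaling, 261 and 218 after quantile normalization, and 239 and 76 relative to nuclear reads. All 340 genes shared by the scaled and unscaled calls kept their direction. Camera called 14 of 29 lists, all up relative to the other genes, and 1 held with an estimated correlation, macrophages (adjusted p = 8.93e-15, and adjusted p = 0.0155 with the estimated correlation). On scaled values none held with it, macrophages at 0.185 and cell cycle lowest at 0.0972. Under all 3 scalings 7 were called: macrophages, interferon-stimulated genes (adjusted p = 6.33e-12; with an estimated correlation 0.228), mitochondrial genes (5.47e-16; 0.152), cell cycle (1.99e-08; 0.136), chemokines (2.35e-07; 0.183), antigen presentation (3.01e-07; 0.244) and mast cells (4.54e-05; 0.228). The scaled list means of macrophage, interferon and cell cycle genes lay above every Model library in all 5 LIPUS libraries (exact permutation p = 0.00794, adjusted p = 0.0276). Those of mitochondrial genes, chemokines, antigen presentation and mast cells had an exact p of 0.0159, 0.0238, 0.0317 and 0.0556 and an adjusted p of 0.0531, 0.074, 0.0921 and 0.134. As deposited, 4.76% of single tested genes separated LIPUS from Model. The margin for interferon genes was narrow, with LIPUS_6 at 1.96 and Model_6 at 1.92. The other 7 lists, luminal, basal, T cell, Schwann cell and adipocyte genes (adjusted p = 0.00918 each; with an estimated correlation 0.475, 0.385, 0.244, 0.327 and 0.475), extracellular matrix (0.00916; 0.523) and seminal vesicle (0.0313; 0.523), lost their call under at least 1 of the 3 scalings and without Model_7 (adjusted p = 0.0606 to 0.744). Without LIPUS_10 the T cell, Schwann cell, adipocyte and seminal vesicle calls also ended (0.0594, 0.201, 0.0739 and 0.259), the last also without LIPUS_6 (0.0517) or LIPUS_8 (0.293). The exact test of the list mean passed for none of these 7 (smallest adjusted p = 0.074). Of the members of these lists Cd4 (relative change 2.62), Krt14 (2.16) and Andpro (4.36; scaled, adjusted p = 0.0511) rose, while the luminal keratin Krt18 (−0.59), Thbs1 (−0.89; scaled, 0.124) and Plin4 (−1.19; scaled, 0.0716) were lower. The median change of the luminal, T cell, basal and extracellular matrix lists lay below 0 as deposited and above 0 relative to the median gene.

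The count of genes between LIPUS and Model depends on single libraries and on the spread that Control lends to the fit. It was 3 with only the 10 samples of both groups in the fit and 77 with the ventral to dorsolateral ratio in the fit. It was 8, 10, 22, 23 and 250 without Model_9, Model_10, LIPUS_6, Model_8 and Model_6. It was 1077 to 1158 without each of the 5 Control libraries, 1179 without LIPUS_10, 4029 without Model_7 and 4576 without LIPUS_7.

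**Figure D4:**
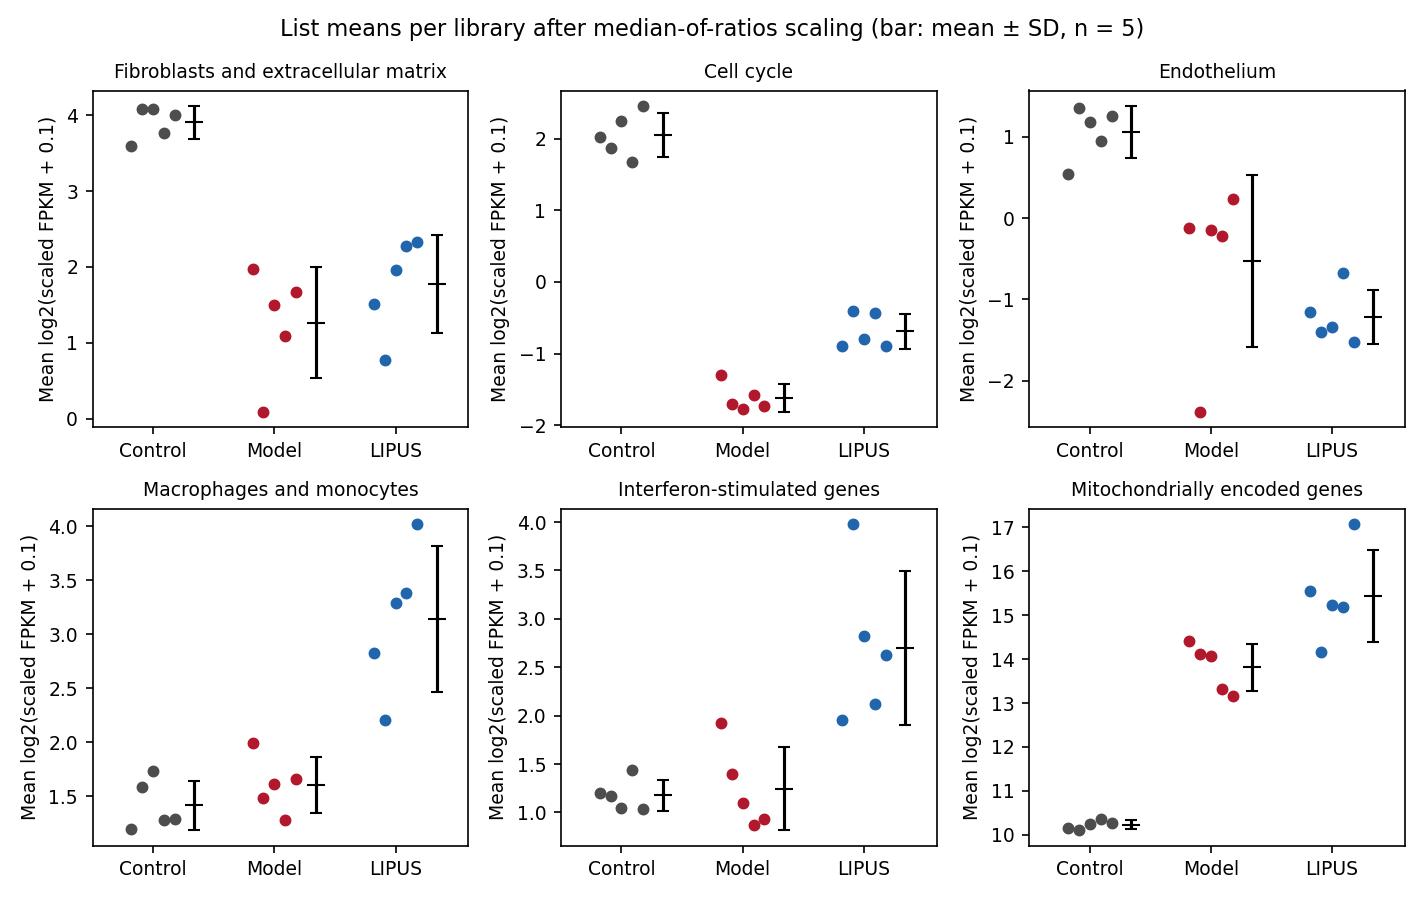
Mean log2(FPKM + 0.1) after median-of-ratios scaling over the tested members of 6 gene lists in each library, with the group mean and SD (n = 5). Macrophage and interferon means of the 5 LIPUS libraries lie above those of all 5 Model libraries, and cell cycle means fall from Control to Model with LIPUS between them.

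Set against untreated controls, LIPUS prostates held less transcript of dividing cells, vessels and matrix and more of macrophages, relative to the median gene. All 17 cell cycle genes, all 10 endothelial genes, all 16 mechanosensing genes and 20 of 21 extracellular matrix genes were lower, counts that were the same when adjusted over the list alone and 16, 9, 7 and 15 after scaling. These 4 calls ended with an estimated correlation as deposited (camera adjusted p = 0.0713, 0.39, 0.259 and 0.221), and on scaled values cell cycle held (0.00256). Col1a1 was at 3.62 ± 0.886 FPKM against 177 ± 63.1 (relative change −4.06, SE 0.38, adjusted p = 8.61e-08), Col3a1 had a relative change of −3.29, Cdh5 −3.45, Kdr, the main receptor for vascular growth factor, −2.73, and Piezo1 −2.44. Yap1 had a relative change of −0.31 (scaled, adjusted p = 0.27). Of the macrophage genes 6 rose and 1 fell (9 and 0 after scaling; camera adjusted p = 0.00395 with an estimated correlation, 0.254 on scaled values): C1qa went from 20.1 ± 3.13 to 43.8 ± 8.06 FPKM (relative change 2.60, SE 0.31, adjusted p = 0.00448), C1qb had a relative change of 2.41 and the lysosomal marker Cd68 one of 3.07, while Cd14 was lower as deposited and level with the median gene (−0.08; scaled, adjusted p = 0.766). Of the interferon genes 4 rose and 3 fell as deposited, and 15 rose and 1 fell after scaling (0.0883 by the same test): Irf7 went from 6.33 ± 1.47 to 45.9 ± 35.1 FPKM (relative change 3.98, SE 0.45, adjusted p = 0.000224), while Ifit1 fell (−1.97). Stat2 was lower as deposited and at −0.12 after scaling. Of 16 antigen presentation genes 1 rose and 3 fell as deposited (0 and 1 adjusted over the list alone), and 6 rose and 0 fell after scaling (0.259 by the same test), with the immunoproteasome gene Psmb8 at a relative change of 2.49 and Tap2 at −0.72 (scaled, adjusted p = 0.171). The eosinophil attractant Ccl11 rose from 1.26 ± 0.775 to 14.3 ± 16.6 FPKM (4.38), while the chemokine genes Cxcl14 and Cx3cl1 fell (−1.67 and −1.52). Cd3g rose (2.84) in the T cell list, 1 of 5. Adjusted over the list alone, the counts were 6 higher and 1 lower for macrophages, 1 and 1 for interferon genes, 2 and 4 for chemokines and 0 and 0 for T cells.

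By the same limits, the 8 highest changes between LIPUS and Control were in the mitochondrial genes ND3 (6.05), COX2 (5.89), ND6 (5.50), ND2 (5.47), ATP6 (5.25) and ND4 (5.12), the neuropeptide gene Npff (5.57) and Gpnmb, a gene of lipid-laden macrophages and other cells (1.47 ± 0.320 to 44.2 ± 49.6 FPKM, 5.28). The 8 lowest were, by these limits, Lao1 (−5.23), the fatty acid desaturase Scd (−4.46), the basement membrane collagen Col4a1 (−4.45), Top2a (−4.22), Col1a1, Pclaf (−4.02), the long noncoding RNA H19 (−4.00) and Slc5a8 (−3.99). Scd and H19 varied widely among Control libraries (73.3 ± 81.1 and 19.8 ± 24.8 FPKM). Limma called 9415 of 12490 genes (119 higher, 9296 lower; 8665 at 2-fold or more; 9723 at an unadjusted p under 0.05), with 1448 higher and 1780 lower after median-of-ratios scaling, 1710 and 1554 after quantile normalization, and 1028 and 1782 relative to nuclear reads. Scaled and unscaled fits shared 1899 calls in the same direction, and 304 genes called in both turned direction, so directions near the median gene rest on the scaling. Camera called 13 of 29 lists, 9 up and 4 down, and 2 held with an estimated correlation: mitochondrial genes (adjusted p = 3.19e-88, and adjusted p = 0.000652 with it) and macrophages (1.71e-17 and 0.00395). On scaled values both ended with it (0.177 and 0.254), and cell cycle genes held (0.00256). The others were interferon-stimulated genes (6.07e-19; with an estimated correlation 0.0883), seminal vesicle genes (5.82e-08; 0.09), antigen presentation (2.21e-06; 0.259), T cells and chemokines (2.92e-05 each; 0.0713 and 0.221), erythrocyte (0.00929; 0.454) and urothelial genes (0.0287; 0.342) up, and cell cycle (1.43e-08; 0.0713), extracellular matrix (2.85e-08; 0.221), mechanosensing (0.000693; 0.259) and endothelial genes (0.00194; 0.39) down. Chemokine, seminal vesicle, erythrocyte and urothelial lists lost their call under each of the 3 scalings and T cells after median-of-ratios scaling (0.0696). The erythrocyte call ended without LIPUS_10 (0.0985), and the urothelial call without Control_6, Control_8, Control_9 or LIPUS_10 (0.0784, 0.092, 0.0903 and 0.186). The medians of the chemokine, antigen presentation, erythrocyte and urothelial lists lay below 0 as deposited and above 0 relative to the median gene. The mitochondrial, macrophage, interferon, antigen presentation, cell cycle, extracellular matrix, mechanosensing and endothelial means after scaling separated all 5 LIPUS from all 5 Control libraries (exact permutation p = 0.00794, adjusted p = 0.0276). So did 3 lists that camera did not call, all lower in LIPUS: basal cells (−0.96), pain mediators and receptors (−1.47) and angiogenic and growth factors (−0.82; adjusted p = 0.0276 each). As deposited, 59.8% of single tested genes separated LIPUS from Control, so separation alone does not set these lists apart.

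**Figure D5:**
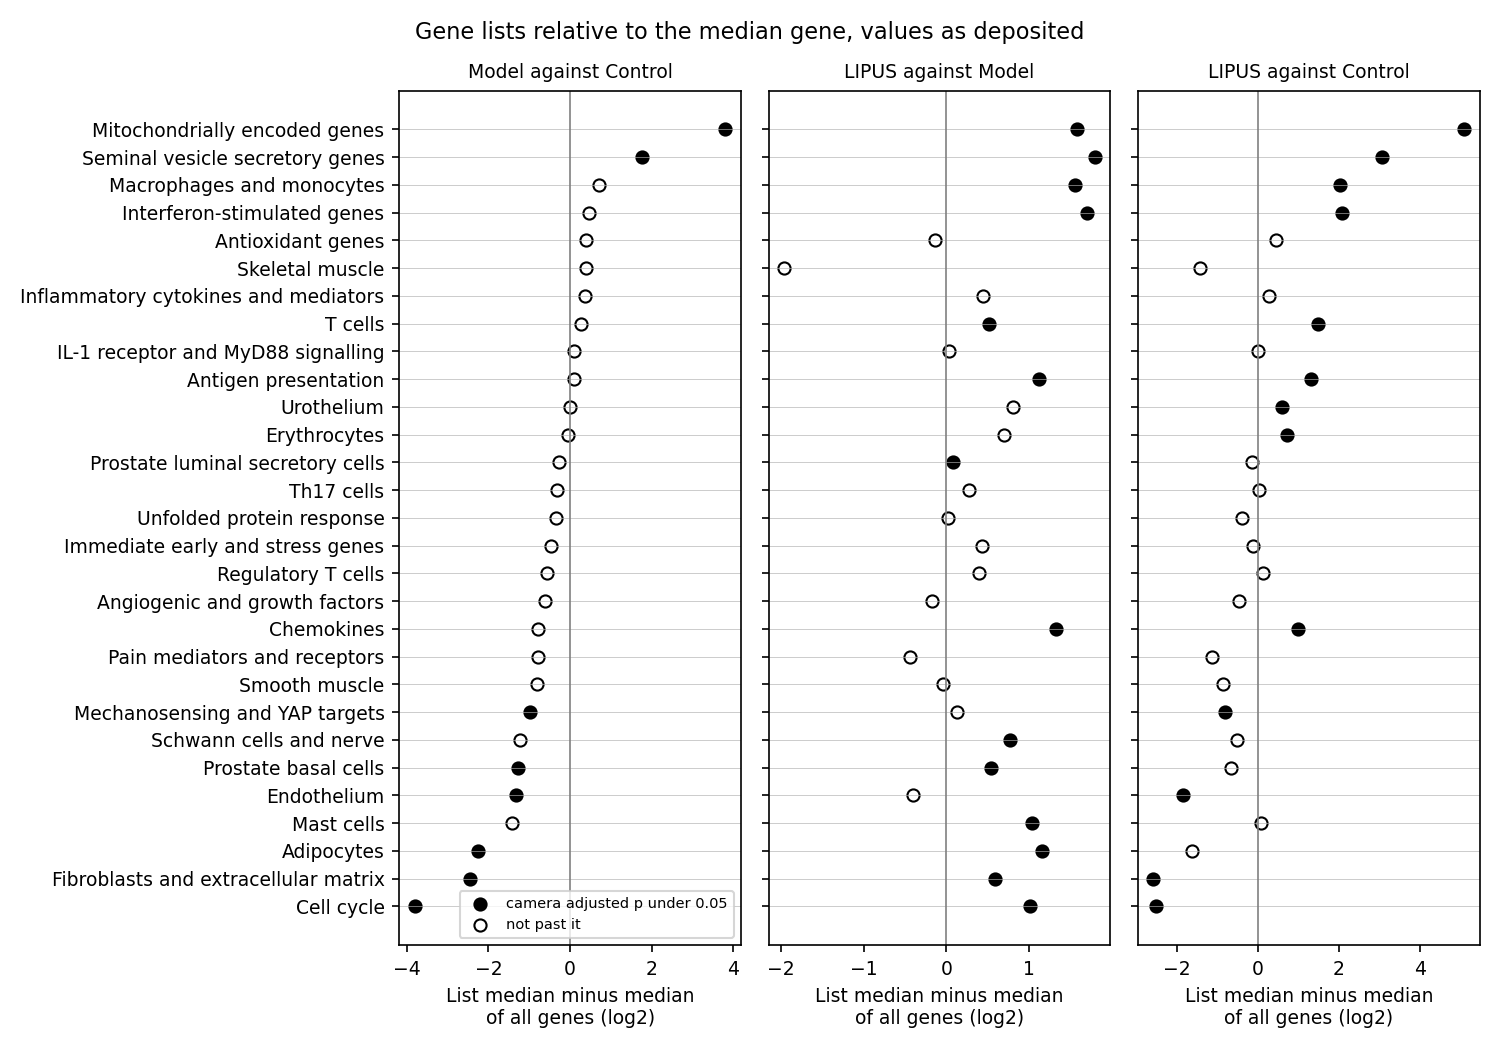
Median log2 change of each of the 29 tested gene lists minus the median over all tested genes, in the 3 comparisons, from values as deposited (filled points: camera adjusted p under 0.05). The cell cycle median lies at −3.81 in Model against Control, at 1.01 in LIPUS against Model and at −2.51 in LIPUS against Control.

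As deposited, camera called the other lists fixed beforehand in none of the comparisons, except the Schwann cell, erythrocyte and urothelial calls given above, although single members passed. Most of these members were lower as deposited, as was the median gene, so the counts after median-of-ratios scaling stand beside them. In the order Model against Control, LIPUS against Model and LIPUS against Control, members higher and lower were 0 and 2, 1 and 1, and 0 and 4 of 6 Th17 genes (scaled 0 and 0, 1 and 0, and 1 and 0; camera adjusted p = 0.937, 0.427 and 0.338). They were 0 and 4, 0 and 0, and 0 and 5 of 7 regulatory T cell genes (scaled 0 and 3, 0 and 0, and 0 and 2; 0.752, 0.176 and 0.603). They were 0 and 11, 0 and 3, and 0 and 20 of 25 genes of IL-1 receptor and MyD88 signalling (scaled 1 and 4, 1 and 0, and 2 and 3; 0.937, 0.604 and 0.62). Stat3, which acts downstream of IL-6 and IL-23, fell in Model (relative change −0.60; scaled, adjusted p = 0.0702). The 5 genes of inflammatory cytokines and mediators gave 0 and 2, 0 and 0, and 0 and 2 (scaled 0 and 1, 0 and 0, and 1 and 0; 0.9, 0.176 and 0.172). The 4 genes of pain mediators and receptors gave 0 and 3, 0 and 1, and 0 and 4 (scaled 0 and 1, 0 and 0, and 0 and 1; 0.45, 0.53 and 0.13). Their list mean passed the exact test against Control in Model and in LIPUS (adjusted p = 0.0276 each). Immediate early and stress genes gave 0 and 9, 0 and 2, and 0 and 11 of 14 (scaled 1 and 5, 2 and 0, and 0 and 1; 0.502, 0.233 and 0.813). The unfolded protein response gave 0 and 13, 0 and 2, and 0 and 17 of 19 (scaled 2 and 2, 0 and 0, and 2 and 2; 0.45, 0.746 and 0.273). Antioxidant genes gave 1 and 4, 1 and 2, and 0 and 10 of 19 (scaled 2 and 3, 1 and 0, and 3 and 0; 0.26, 0.604 and 0.0728). Angiogenic and growth factors gave 0 and 9, 1 and 2, and 0 and 11 of 14 (scaled 1 and 2, 1 and 1, and 1 and 4; 0.643, 0.974 and 0.621), with the list mean past the exact test in LIPUS against Control (adjusted p = 0.0276). Smooth muscle gave 0 and 8, 0 and 0, and 0 and 12 of 14 (scaled 0 and 3, 1 and 0, and 0 and 3; 0.242, 0.401 and 0.26), and skeletal muscle 0 and 1, 0 and 0, and 0 and 3 of 11 (scaled 0 in all; 0.0902, 0.62 and 0.104). Schwann cell genes fell for 11 of 12 members in Model against Control without a call (3 scaled; 0.0851; exact test of the list mean, adjusted p = 0.0276), and for 8 in LIPUS against Control (3 scaled; 0.964). Urothelial and erythrocyte genes had no member past the threshold in any comparison, as deposited or scaled.

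Other settings called some of the lists that were not called as deposited. With the ventral to dorsolateral ratio in the fit, an alternative added after the data were seen, camera called regulatory T cell genes up in LIPUS against Model (adjusted p = 0.00815; scaled, 0.00887), with 0 of 7 members past the threshold as deposited and 1 scaled. The ratio varied most within Model (SD 6.61, against 1.82 in Control and 2.02 in LIPUS), where Model_7 stood apart at 7.76. How far the calls of this fit rest on Model_7 was not tested. In the same fit chemokines and mast cells (0.0169 and 0.0273), Schwann cells (0.00945) and angiogenic factors (0.0136) were called down in Model against Control, and inflammatory cytokines, urothelium and erythrocytes up in LIPUS against Model (0.0199, 0.000296 and 4.59e-05). It also called smooth muscle and the unfolded protein response in all comparisons, down against Control in Model (2.65e-05 and 7.48e-05) and in LIPUS (0.00232 and 0.00261) and up in LIPUS against Model (0.000214 and 0.00598). Quantile normalization called these 2 lists down against Control in Model (0.00977 and 0.000846) and in LIPUS (0.00279 and 0.000425), together with luminal genes (0.0208 and 0.0285), and in LIPUS also adipocyte (0.015) and pain genes (0.0275). Adipocyte genes in LIPUS against Control also passed after median-of-ratios scaling (0.0234) and relative to nuclear reads (0.0281), as did pain genes relative to nuclear reads (0.0463), and skeletal muscle genes passed as lower in LIPUS than in Model relative to nuclear reads (0.0204). Without Model_7 the unfolded protein response was called down in LIPUS against Model (0.00756) and against Control (0.00832), and so it was without Model_7 and LIPUS_10 (0.00704 and 0.0125). In LIPUS against Model this direction is opposite to that with the ratio in the fit (0.00598). Without Model_7 endothelial genes were called down in LIPUS against Model (0.0275) and smooth muscle in LIPUS against Control (0.0158). Interferon genes were called up in Model against Control without Model_9 or Model_10 (0.0449 and 0.0377), and Schwann cell genes down without Control_6, Control_10 or Model_8 (0.0247, 0.0292 and 0.0405). Skeletal muscle was called up there without Control_9, Control_10 or Model_7 (0.0196, 0.0256 and 0.024), and in LIPUS against Control without Control_9, Control_10 or LIPUS_7 (0.0389, 0.0386 and 0.00565). Erythrocyte genes were called up in LIPUS against Model without Model_6, Model_8, Model_10, LIPUS_7 or LIPUS_8 (0.0053, 0.0345, 0.03, 0.0164 and 0.00511). Luminal and antioxidant genes were called up in LIPUS against Control without LIPUS_7 (0.034 and 0.0408) or LIPUS_8 (0.0261 each).

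To see whether treatment moved genes of the model back, both steps were set side by side. Of the tested genes, 305 were called in Model against Control and in LIPUS against Model in opposite directions, 190 up and then down and 115 down and then up, where independent lists of these sizes would share 48.8 and 70.2. Another 186 moved the same way in both steps, 179 of them down, where independent lists would share 714 lower genes. The Model samples enter both steps, and part of the opposite count may come from this. The genes with the strongest support in both steps all fell in Model and rose in LIPUS. Of these, 7 stayed below Control: Ccna2, Sntb1 (a membrane scaffold gene; 3.64 ± 1.29, 0.0225 ± 0.0389 and 0.598 ± 0.239 FPKM in Control, Model and LIPUS; SD, n = 5), Selp (7.80 ± 8.40, 0.132 ± 0.126 and 3.18 ± 0.901 FPKM), Cpa3, the vitamin B12 carrier Tcn2, the cytokine receptor gene Il13ra1 and the matrix gene Ogn. RT1-Bb came to 1.72 ± 0.377, 0.330 ± 0.0821 and 1.76 ± 0.688 FPKM. Their relative changes were −5.10 to −1.19 in Model against Control and 2.32 to 4.54 in LIPUS against Model. Across genes, which are not independent replicates, the log2 changes of both steps had a correlation of −0.588 and a covariance of −0.571. Sharing the Model samples alone gave a mean correlation of −0.465 (−0.886 to 0.168, a range that holds the observed value) and a mean covariance of −0.0901 in 100 simulations of unchanged groups, so the covariance differed from the simulated value by −0.481. These simulations mixed the spread of all 15 libraries and do not hold that of the Model libraries alone, so this difference may be too large. With disjoint parts of the Model samples in each step, over 20 divisions, the correlation averaged −0.354 (−0.48 to −0.133) and the covariance −0.398. The count of opposite genes was 5, 6, 13, 14 and 88 without Model_9, Model_10, Model_8, LIPUS_6 and Model_6, 175 to 198 without each Control library, 473 without LIPUS_7 and 967 without Model_7, after scaling it was 333 (128 up and then down, 205 down and then up), and with the ventral to dorsolateral ratio in the fit it was 46.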

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

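The tests that weigh gene numbers, lobes and gene length, the assignments that keep Control and the nuclear scaling were chosen only after the results had been seen. The other splits of the samples, the exact test of list means, the other scalings and the fits without a library were fixed before, while the use of these scalings and fits to weigh a pattern was not. A library was marked where its gap to the nearest of the other 4 in its group made up an unusually large part of the group's range by Dixon's test, and the ratio of gap to range is given for each. Genes and lists were compared as log2 values. Of 522 groups tested 54 were marked, 10.3%, where chance marks about 1 in 20. Model_7 had 25 of these marks, Control_8 6, LIPUS_10 5, Model_10 4 and LIPUS_8 3.

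Model_7 was the highest Model library in ventral secretory reads (ratio 0.742; 5.16% against 0.0199% to 1.345%), Cd68 (0.766; 12.3 against 1.74 to 2.78 FPKM) and Stat2 (0.76; 9.14 against 2.71 to 3.64 FPKM). It was the lowest in the dorsolateral genes Msmb (0.941; 4.63 against 23584 to 40320 FPKM) and Pbsn (0.894; 304 against 71781 to 137386 FPKM), in Stat5a (0.86; 2.83 against 58.3 to 95.1 FPKM), and in the list means of inflammatory cytokines (0.752), antigen presentation (0.753), seminal vesicle genes (0.723), urothelium (0.766), endothelium (0.826), pain mediators (0.751) and the unfolded protein response (0.765). It was also the lowest in Best1 (0.714), Ccdc152 (0.774), Cldn5 (0.82), Col4a1 (0.762), Herpud1 (0.772), Lamc1 (0.721), Pdzk1ip1 (0.897), Plin4 (0.89), Svs4 (0.943), Tapbp (0.742), Thbs1 (0.736) and Vegfc (0.754).

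Among the other Model libraries, Model_6 was highest in the percent of detected genes with 1 read (0.74), Model_8 lowest in Ctss (0.749), Model_9 lowest in Adipoq (0.73) and Csf1r (0.734), and Model_10 highest in the Th17 list mean (0.77) and in Rrm2, Tnf and Top2a, which had reads in no other Model library (ratio 1 each). Control_6 was lowest in the mechanosensing mean (0.899). Control_7 was highest in Semg1 (0.762; 12.9% of reads against 0.053% to 3.11%) and alone in Il17a reads (ratio 1). Control_8 was highest in Cxcl13 (0.79), Il13ra1 (0.726), ND3 (0.727) and Il6 (ratio 1) and lowest in Acsl4 (0.722) and Cx3cl1 (0.776). LIPUS_6 was lowest in the chemokine mean (0.719) and alone in Il10 reads (ratio 1), LIPUS_7 alone in Kdr reads (1), and LIPUS_9 alone in Tnf reads (1). LIPUS_8 was alone in Ifit1 reads (1), highest in Il13ra1 (0.783) and lowest in Tap2 (0.742). LIPUS_10 was highest in Gsdma (0.891) and lowest in F2rl1 (0.716), Lao1 (0.731), Pdzk1ip1 (0.73) and Rrm2 (0.747).

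The bound for excluding chance was set beforehand at fewer than 5 of 100 splits with as many genes, the real one included. By it chance can be excluded for the counts of genes in Model against Control (1 split; 5750, highest other 1985) and LIPUS against Control (1 split; 9415, highest other 6322). For opposite genes, assignments of all 15 samples decide nothing (1 of 100; 305, highest other 1), since breaking up Control leaves hardly any gene called in both steps. With Control kept, 7 of 100 assignments of the Model and LIPUS samples gave as many (305, highest other 3042), among them the exchange of both groups as a whole, so chance cannot be excluded for this count. For LIPUS against Model 4 splits gave as many genes (1820, highest other 3854), which meets the bound. The other 3 all put Model_7 with 4 LIPUS libraries and a LIPUS library with the other 4 Model libraries. The samples thus hold a structure beside the groups that gives larger counts, and with only both groups in the fit the count was 3. Chance cannot be excluded for the counts of lists either, reached in 76 of 100 splits (8, highest other 19), 33 (14, highest other 20) and 28 (13, highest other 17).

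Fewer genes were detected in Model than in Control. Mitochondrial reads could take the place of nuclear ones, but at equal nuclear reads the difference was still −1817 genes (exact permutation p = 0.00794). Fewer independent molecules per library may account for it: genes with exactly 1 read made up at most 2.38% of detected genes in a Model library and at least 5.54% in a Control library. RNA quality and the amount of RNA were not measured here, so a loss of cell types remains possible beside it.

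Extracellular matrix and cell cycle genes were lower in Model than in Control. The extracellular matrix call was lost with an estimated correlation (adjusted p = 0.361; scaled, 0.451). Another mixture of prostate lobes could shift both, but with the ventral to dorsolateral ratio in the fit the larger camera adjusted p of both lists was 6.08e-12. A loss of long or weakly expressed genes is unlikely to account for it: the middle 95% of random lists matched on length and expression had medians down to −1.78, while the higher of the list medians was −3.36. The ratio of secretory reads measures lobes only indirectly, so a change in tissue make-up that this ratio does not follow remains open. Its spread within groups was largest in Model, where Model_7 stood apart, and the fit with the ratio was not repeated without that library.

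Macrophage and interferon genes were higher in LIPUS than in Model. Scaling could produce this, but the largest camera adjusted p of both lists over 3 scalings was 1.12e-08, and over 15 fits without a library each it was 8.56e-08. With the lobe ratio in the fit the larger p was 4.05e-12, although members past the threshold went from 6 to 1 and from 2 to 0 (8 and 6 scaled) and all genes called from 1820 to 77. The relative median went from 1.56 to 1.65 for macrophage genes and from 1.70 to 1.57 for interferon genes. The limits of the ratio, among them its dependence on Model_7, hold here as well. Genes of a list that vary together may make camera's p too small (0.0155 and 0.228 with an estimated correlation; scaled, 0.185 and 0.352), yet the list means of all 5 LIPUS libraries lay above all Model libraries (exact permutation p = 0.00794 for both). For interferon genes the lowest LIPUS library lay barely above the highest Model library (LIPUS_6 at 1.96, Model_6 at 1.92), and LIPUS_7 was highest at 3.98. More immune cells and more transcript per cell could each give this pattern, and whole tissue cannot tell them apart.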

How the results depend on the processing

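The nuclear scaling, limma-voom, the removal of Model_7 with LIPUS_10, the lobe ratio (ventral to dorsolateral reads) in the fit and the estimated correlation on scaled values were chosen only after results had been seen. Depth limits the series' genes: 0 reads allowed up to 0.353 FPKM of Il17a in a LIPUS library. This bound uses a recovered gene length of 286 bp, which rests on a single library with reads of Il17a and may be too short, so the bound may be too high. The cause of the changes below was not tested, except where fewer samples or genes in the fit show it. Of 86 named genes in Model against Control, 78 kept their direction and their side of the threshold after median-of-ratios scaling and 8 no longer passed. Of 96 in LIPUS against Model, 68 did, 22 no longer passed and 6 newly passed, and with only 2 groups in the fit 37 did. Of 96 in LIPUS against Control, 73 did, 17 no longer passed, 1 newly passed and 5 reversed.

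Genes called between LIPUS and Model (1820) came to 526 with median-of-ratios scaling, 479 with quantile normalization, 315 relative to nuclear reads, 812 without a filter, 3 with only the groups compared in the fit, 3637 with array weights, 81 with limma-voom, 77 with the lobe ratio and 4225 without Model_7 and LIPUS_10, and to 8 to 4576 with 1 library left out. Between Model and Control they came to 8953 with array weights and 4402 to 6970 with 1 library left out. Between LIPUS and Control they came to 3228, 3264 and 2810 with the 3 scalings, 3195 with limma-voom and 8239 to 10078 with 1 library left out.

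Lists called in Model against Control came to 4 with a pseudocount of 0.01, 5 with only the groups compared, 5 with array weights, 13 with the lobe ratio, 2 with an estimated correlation (1 scaled), 23 with fry, and 4 to 9 with 1 library left out (4 without LIPUS_10). In LIPUS against Model they came to 8, 7 and 9 with median-of-ratios, quantile and nuclear scaling, 8 with array weights, 7 with limma-voom, 8 without Model_7 and LIPUS_10, 1 with an estimated correlation (0 scaled), 20 with the lobe ratio, 2 with fry, and 9 to 15 with 1 library left out (9 without Model_7). In LIPUS against Control they came to 8 with limma-voom, 2 with an estimated correlation (1 scaled), 20 with fry, and 11 to 16 with 1 library left out.

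The index difference of Model against Control (0.107) was 0.524 with the stricter filter and turned to −0.144 with a pseudocount of 0.01 and −0.128 without Model_7 and LIPUS_10 (−0.128 to 0.292 with 1 library left out). That of LIPUS against Model (−0.00179) was −0.687 with the stricter filter and turned to 0.0645 with a pseudocount of 1 and 0.677 without both libraries (−0.179 to 0.549). That of LIPUS against Control turned to −0.292 with a pseudocount of 0.01, −0.071 with median-of-ratios scaling, −0.163 with the stricter filter and −0.146 relative to nuclear reads (0.0275 to 0.495). None passed its exact test. Of the 30 exact tests of the series' genes 11 passed after quantile normalization, some of them genes with 0 to 10 reads per group, and 0 to 0 with 1 library left out.

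Opposite genes in both steps (305) came to 174 without a filter, 1068 with array weights, 192 relative to nuclear reads, 55 with limma-voom, 46 with the lobe ratio, 1570 without Model_7 and LIPUS_10, and 5 to 967 with 1 library left out. The correlation of both steps was −0.547 with a pseudocount of 1, −0.537 with median-of-ratios and −0.543 with quantile scaling, −0.373 without a filter, −0.648 with array weights, −0.517 relative to nuclear reads, −0.542 with limma-voom, −0.683 without both libraries, and −0.692 to −0.539 with 1 library left out.

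In LIPUS against Control, log2 changes below 0 as deposited turned positive with median-of-ratios, quantile, nuclear scaling and limma-voom, in this order: Myd88 0.38, 0.48, 0.31 and 0.42, Rora 0.0901, 0.50, 0.0293 and 0.0665, Il33 0.21, 0.19, 0.13 and 0.15, and Tapbp 0.24, 0.15, 0.17 and 0.25. Tgfb1 turned to 0.0356 and 0.22 with the first of these and quantile scaling, Lck to 1.59 with quantile scaling, and Stat2 to 0.0190 with limma-voom. In Model against Control Svs4 turned to −2.51 with the lobe ratio, and in LIPUS against Model 45 of the 96 named genes no longer passed with it.

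With the replicate number as a block, LIPUS against Model gave 3 genes and 2 opposite genes. Of its 96 named genes 36 kept their side of the threshold and 60 no longer passed, and the counts of genes and lists in the other comparisons moved by less than 1.5 times. The pairing has no source in the labels: 4 of 15 pairs of same-numbered samples correlated above 0.1 (−0.417 to 0.249), and 0 of 15 samples correlated best with its own number.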

Other observations

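All tests of this part were chosen only after results had been seen, except the matched-list test of ribosomal genes, whose prediction was written before it was run. Among 311 KEGG pathways, sets picked for description here after their values were seen, Model samples had more transcript of the protein-making machinery than Control, relative to the median gene. Of 162 ribosome genes 86 were higher and 2 lower as deposited, and 142 higher and 0 lower after scaling (limma camera adjusted p = 3.17e-55; adjusted p = 0.9987 with an estimated correlation). Rpl21 went from 262 ± 34.2 to 677 ± 125 FPKM and Rpl8 from 385 ± 46.2 to 813 ± 101.1 FPKM (SD, n = 5). The median log2 change of the ribosome genes was 0.84, and the middle 95% of 10000 random lists matched on length and mean expression reached 0.0887. Gene length, as far as it was matched, thus did not account for it. The matching used coarse bins without ribosome genes and drew genes independently. An effect particular to the shortest genes is therefore not excluded (median length 725 bp for ribosome genes, 3004 bp for all genes). Of 131 oxidative phosphorylation genes, 24 were higher and 21 lower, and 75 and 5 after scaling (adjusted p = 2.89e-12; adjusted p = 0.9987 with an estimated correlation). The 13 mitochondrially encoded genes described for the libraries are part of this set and all among the higher ones, beside them the nuclear genes Ndufa6 (108 ± 14.1 to 191 ± 30.1 FPKM) and Atp5f1e (192 ± 18.2 to 606 ± 216 FPKM). Of 54 genes of ECM-receptor interaction 47 were lower and 30 after scaling (5.78e-11; adjusted p = 0.9987 with an estimated correlation), with the basement membrane genes Lamc1 (19.4 ± 4.85 to 0.869 ± 0.345 FPKM) and Col4a2 (19.6 ± 4.93 to 0.328 ± 0.176 FPKM), as were 108 of 156 focal adhesion genes (scaled, 10 higher and 70 lower; 1.39e-05) and 80 of 123 axon guidance genes (scaled, 5 higher and 51 lower; 0.000882), both with an adjusted p of 0.9987 with an estimated correlation.

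Between LIPUS and Model samples, camera called complement, phagosome and natural killer cell pathways as higher in LIPUS relative to the other genes, and none of these calls held with an estimated correlation (adjusted p = 0.9988 each). Of 43 complement and coagulation genes 9 were higher and 1 lower, and 11 and 0 after scaling (limma camera adjusted p = 1.15e-10). Of 130 phagosome genes 11 were higher and 11 lower, and 16 and 1 after scaling (3.29e-05), with the lysosomal protease gene Ctss from 10.4 ± 2.54 to 21.6 ± 4.61 FPKM (SD, n = 5). Of 79 genes of natural killer cell cytotoxicity 3 were higher and 5 lower, and 7 and 0 after scaling (5.82e-05), with the receptor subunit gene Fcer1g from 5.72 ± 2.97 to 15.6 ± 3.91 FPKM and Cd48 from 2.05 ± 1.09 to 6.49 ± 1.18 FPKM. Of 29 propanoate metabolism genes 13 were lower and 2 after scaling (0.0089; adjusted p = 0.9988 with an estimated correlation). In all, 44, 41 and 72 pathways were called in Model against Control, LIPUS against Model and LIPUS against Control (39, 45 and 64 after scaling), and 0 held with an estimated correlation (smallest adjusted p = 0.9987, 0.85 and 0.995).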
